A study of Mus musculus with 10 samples.

How the data were processed

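The series holds RNA sequencing of tumours of TH-MYCN mice. Per the labels, tumours were flash frozen, RNA was extracted with Trizol and libraries of polyadenylated RNA were prepared with NEB protocols. The files hold whole-number counts per Ensembl gene, 1 column per library, as deposited. Per the submitters' processing notes, the genome build was mm10 and the tools were TopHat2 2.1.1, HISAT2 and edgeR, without the role of each. The read counter, its annotation, its strand setting and its treatment of reads with several alignments are not given in the sources used here. Totals differed by 2.1% between libraries. A step that takes equal numbers of reads per library is not given in the sources used here.

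Each of the 10 columns was matched to a sample of the labels, and 0 were left unmatched. Groups were untreated (n = 3), 24 h of the combination (n = 3) and 5 days of the combination (n = 4). Of 54446 gene identifiers, 54409 had a symbol and coordinates in GENCODE release M21 of the mouse genome, and the other 37 held at most 0.0041% of the counts of any library. Genes with near-identical copies, such as histones, ribosomal proteins and MHC genes, are uncertain, because reads could be split between copies. The same holds for genes that overlap on opposite strands.

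Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14956 genes. Library sizes were scaled with TMM, whose factor was 0.812 for 5-day library 1 and 1.001 to 1.039 for the others. A model with 1 mean per group was fitted to all 10 libraries with robust quasi-likelihood dispersions. The 3 comparisons were 24 h against untreated, 5 days against untreated and 5 days against 24 h, each with the quasi-likelihood F test. P-values were adjusted with the Benjamini-Hochberg method over all tested genes, and genes under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. CPM values use the scaled library sizes, and means are given with the SD over libraries.

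Lists of genes, 38 in all, were tested with camera (limma 3.58.1), which compares the genes of a list with all other genes. The correlation between genes was preset to 0.01. Of the 38 lists, 27 had at least 5 tested members and were tested, with p-values adjusted over these 27. The correlation was also estimated from the residuals of each list. Beside counts over all genes, members were adjusted over the list alone. Lists with fewer tested members are described by their summed CPM. List scores are means of log2 CPM after adding 0.5 CPM. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined.

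Genes named in the text were called genes (the 10 highest and 10 lowest by log2 fold change with a mean of at least 5 CPM and no overlap between groups), up to 4 members per list with the smallest unadjusted p, and a fixed set. The set holds Mycn, Myc, Aurka, Atr, Chek1, Cdkn1a, Th, Ptprc, Xist and Ddx3y, and 1 more gene. Some genes that the rule names are not reported here. No gene was called with all libraries, so the first part of the rule named none. Genes outside the rule are said to be chosen after their values were seen.

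The alternatives planned were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter at a mean of 5 CPM, a fit of only the compared groups, the replicate number as a block, each library of the compared groups left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were leaving out 5-day library 1 at 24 h and with an estimated correlation, leaving out 5-day libraries 1 and 2, and limma voom with a quality weight per library. No library was left out with the tests described above.

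The tests were tried on simulated data with 200 changed genes. With the spread of all 10 libraries, edgeR recovered 42.4%, 53% and 56.1% of genes changed 4-fold in the 3 comparisons and 7.5%, 4.5% and 6% of genes changed 2-fold. It made 1, 5 and 0 false calls, and DESeq2 made 45, 46 and 41. With the spread of the 9 libraries without 5-day library 1, edgeR recovered 62.7%, 65.7% and 52.2% of genes changed 2-fold, with 7, 10 and 8 false calls. DESeq2 then made 26, 24 and 24 false calls. A list shifted by 0.5 on the log2 scale was found in each of the 3 comparisons. With the spread of all 10 libraries, 2 of the other lists were called as well at 24 h and 0 in the other comparisons, with 27 lists tested. Simulated genes were drawn independently of each other. These numbers therefore cannot show how many lists are called falsely where the genes of a list are correlated, as in the real data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.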

Results

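Tumours of TH-MYCN mice were profiled by sequencing of polyadenylated RNA. In this strain, neuroblastoma forms in the sympathetic nervous system of animals that carry a human MYCN transgene driven by a tyrosine hydroxylase promoter. Per the labels, 3 libraries came from tumours of untreated mice, 3 from tumours treated for 24 h and 4 from tumours treated for 5 days. The treatment was a combination of MLN8237 (alisertib, an inhibitor of the mitotic kinase Aurora-A) and AZD6738 (ceralasertib, an inhibitor of the replication stress kinase ATR). The sample titles speak of a combination, while the design text joins the names of both drugs with "or". Libraries held 5576926 to 5696436 counts, a range of 2.1%, and 19790 to 21264 genes with at least 1 count. At this depth 3 counts, the limit taken for a gene with none, correspond to a normalised read count (CPM) of 0.527 to 0.538. Intervals and limits of this kind cover counting error only. Nothing in the labels says whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries.

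The tumour libraries shared a sympathetic profile, apart from 1 library of the 5-day group. Summed over 19 genes of adrenergic identity, the 5-day libraries 2, 3 and 4 held 3846, 5214 and 4842 CPM and library 1 held 1330 CPM, against 4867 to 5829 CPM in untreated tumours. Mycn was at 93.6 to 105 CPM in 5-day libraries 2 to 4 and at 21.4 CPM in library 1. Reads of the human transgene that align to the mouse gene cannot be separated from mouse Mycn in these counts. Summed over 16 macrophage markers, library 1 held 13700 CPM, against 807 ± 208 CPM (SD, n = 3) in untreated tumours. Its 14 fibroblast markers summed to 19200 CPM, 11 times the untreated mean, and its 10 adipocyte markers to 9130 CPM. Markers of T cells (143 CPM), B cells (227 CPM), NK and cytotoxic cells (60.4 CPM), dendritic cells (262 CPM), neutrophils (141 CPM) and plasma cells (22.5 CPM) were highest in this library as well. The first principal component carried 70.5% of the variance and placed library 1 at 167.3, with the other 9 libraries between -51.3 and 20.3. Its mean Spearman correlation with the others, across genes, was 0.74, against 0.944 to 0.954 for the others.

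Transcripts of other organs appeared in some libraries. In 5-day library 2, adrenal cortex markers summed to 1940 CPM, hepatocyte markers to 429 CPM and skeletal muscle markers to 525 CPM, against untreated maxima of 76.1, 76.4 and 4.69 CPM. Hepatocyte markers summed to 365 CPM in 5-day library 1 and skeletal muscle markers to 184 CPM in 5-day library 4. Alb, the hepatocyte marker for albumin, chosen after its values were seen, was at 226 CPM in 5-day library 2 and 3.03 CPM in 5-day library 1. The sum in 5-day library 1 thus came almost wholly from other members of the list and does not show RNA of liver. Kidney tubule markers reached 129 CPM in untreated library 3 and 34.4 CPM in 5-day library 1, with 0.873 and 1.74 CPM in the other untreated libraries. Erythroid markers ranged from 174 to 1880 CPM over the 10 libraries without following the groups. The Y-linked gene Ddx3y was at 3.83 CPM in untreated library 2 and 4.97 CPM in 5-day library 1, and at 61.9 to 93.8 CPM elsewhere. The Y-linked genes Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were at 0 CPM in untreated library 2. They were at 0.649 to 0.865 CPM in 5-day library 1 and at 11.2 to 56.2 CPM elsewhere. Low Y-linked values were thus found in untreated library 2 and 5-day library 1 and in no 24 h library. Their part in the comparisons was not tested. Xist and Tsix had 0 counts in all 10 libraries, so these 2 transcripts carry no information on sex here.

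**Figure D1:**
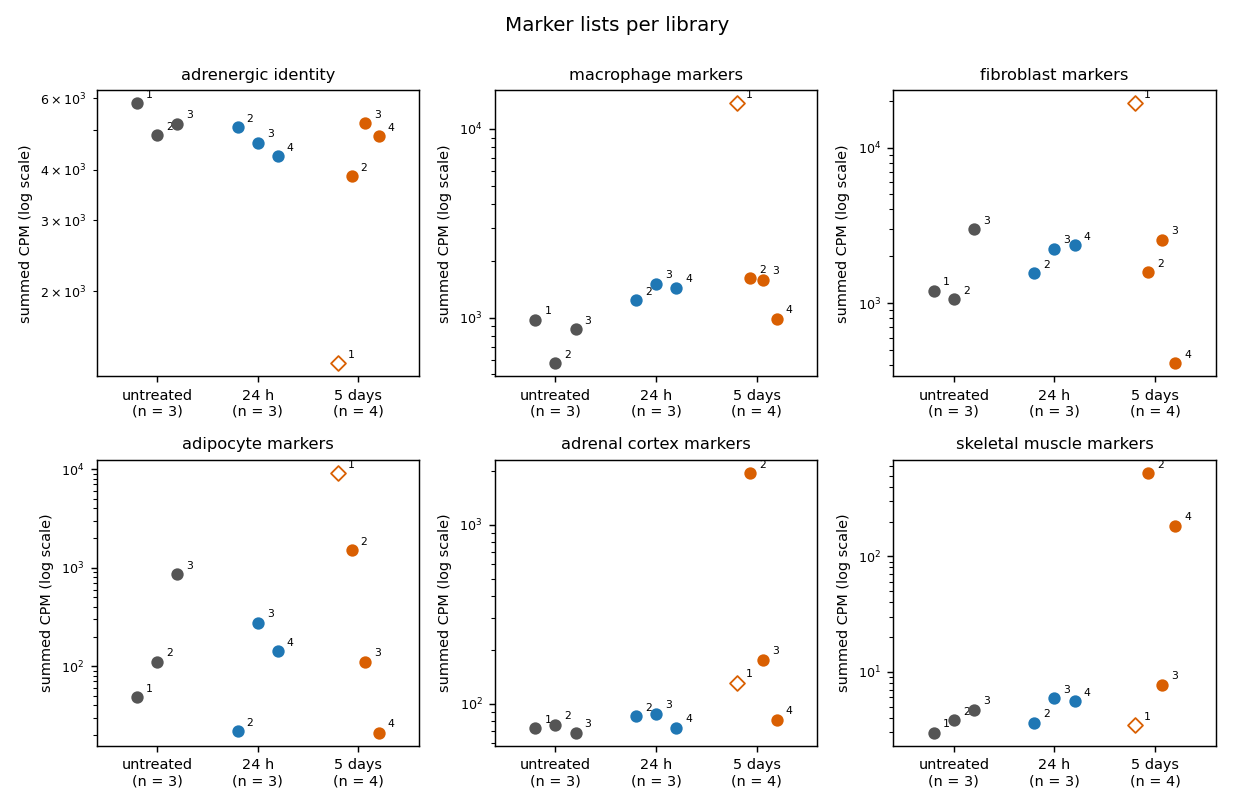
Summed CPM of the genes of 6 marker lists (log scale) in each library, by group (untreated n = 3, 24 h n = 3, 5 days n = 4). Numbers beside points are replicate numbers, and the open diamond is 5-day library 1, which holds 13700 CPM of macrophage and 19200 CPM of fibroblast markers and the lowest sum of adrenergic genes (1330 CPM).

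The comparison of 24 h of treatment with no treatment asks for the early response of the tumours. After 24 h, p53 targets rose together, as did genes of mitosis, replication-dependent histones, Schwann cell and macrophage markers, and interferon and MHC class I genes, while genes of cholesterol synthesis and of the respiratory chain fell. These 9 list calls, made with a preset correlation, were all lost at adjusted p = 0.0804 to 0.892 with an estimated correlation, and no member passed over all genes. With the replicate number as a block, which ties untreated library 1 to 5-day library 1, the mitosis and respiratory chain calls were absent. Their medians then changed sign (-0.06 and 0.06). Sesn2, a stress-induced p53 target, was at 24.8 ± 4.92 CPM (SD, n = 3) at 24 h and at 6.44 ± 0.478 CPM (SD, n = 3) in untreated tumours, a 3.84-fold difference. Aurka, which encodes the drug target Aurora-A, was at 197 ± 26.2 CPM (SD, n = 3) against 129 ± 9.17 CPM (SD, n = 3). Hmgcs1, an early enzyme of cholesterol synthesis, was at 93.2 ± 1.09 CPM (SD, n = 3) against 133 ± 21.5 CPM (SD, n = 3). In the mm10 genome Sesn2 (ENSMUSG00000028893) lies on the minus strand of chromosome 4, from 132492032 to 132510501, and Aurka (ENSMUSG00000027496) on that of chromosome 2, from 172356190 to 172370535.

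No single gene passed the test in the fit of all 10 libraries. Of the 14956 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.05 there were 263 genes (171 higher, 92 lower), where chance gives 748, and DESeq2 called 0. The spread shared by all 3 groups entered this test, and 5-day library 1 set much of it. The biological coefficient of variation was 40.8% with all 10 libraries and 18.9% without that library. Without it, an alternative chosen after seeing the data, 2 genes were higher at 24 h, both at an adjusted p = 0.0297 (edgeR quasi-likelihood, Benjamini-Hochberg). One was Pif1, a DNA helicase gene (ENSMUSG00000041064, chromosome 9, 65587160 to 65595967 on the plus strand of mm10), at 110 ± 16.3 CPM against 56.0 ± 2.22 CPM (SD, n = 3 each). The other was Cep55, a gene of the final cut between daughter cells (ENSMUSG00000024989, chromosome 19, 38055011 to 38074423, plus strand), at 79.5 ± 3.63 CPM against 45.3 ± 3.33 CPM (SD, n = 3 each). With only the untreated and 24 h libraries in the fit, 7 genes were higher and 0 lower. They were Sesn2 and Gpnmb (adjusted p = 0.0183), Cep55, Pif1, Psrc1 and Mmp12 (0.0247) and Trp53inp1 (0.0382), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cep55, Pif1, Psrc1, Gpnmb and Mmp12 were chosen after their values were seen.

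Mitotic genes were higher at 24 h in 36 of 39 tested members of the G2/M list. The list rose with a median log2 fold change of 0.26 (camera with a preset correlation, Benjamini-Hochberg adjusted p = 8.53e-08). With an estimated correlation the call was lost (adjusted p = 0.892 with an estimated correlation). With the replicate number as a block, which ties untreated library 1 to 5-day library 1, the median was -0.06 (adjusted p = 0.337). Log2 fold changes were 0.57 ± 0.21 (SE) for Cdc25b, a phosphatase that drives mitotic entry, 0.57 ± 0.31 for the kinetochore motor Cenpe, 0.61 ± 0.33 for Kif23, a motor of cytokinesis, and 0.61 ± 0.38 for Aurka. Adjusted over the list alone, 0 members passed, as over all genes. Without 5-day library 1, 17 passed over the list alone, and the list had an adjusted p = 0.272 with an estimated correlation. Of the genes of DNA replication and the G1/S transition, 8 were higher and 32 lower (median -0.07, camera adjusted p = 0.0697). Without 5-day library 1 this list fell, with 31 of 40 lower and a median of -0.06 (adjusted p = 0.0075, and adjusted p = 0.847 with an estimated correlation). ATR pathway, Fanconi and homologous recombination genes had a median of -0.11 (adjusted p = 0.407). Atr itself was at 45.7 ± 8.06 CPM against 50.1 ± 8.37 CPM (SD, n = 3 each), and Chek1, the kinase below it, at 48.3 ± 5.93 against 56.8 ± 4.50 CPM (SD, n = 3 each). Chek2, the checkpoint kinase downstream of ATM, chosen after its values were seen, was at 45.2 ± 2.87 against 25.1 ± 3.07 CPM (SD, n = 3 each).

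p53 targets were higher in 24 of 26 tested members, and the list rose by a median log2 fold change of 0.46 (camera, adjusted p = 2.65e-13). The call was lost at adjusted p = 0.146 with an estimated correlation. Bbc3, which encodes the death protein PUMA, was at 56.0 ± 7.45 CPM (SD, n = 3) against 31.9 ± 4.50 CPM (SD, n = 3), and its log2 fold change was 0.81 ± 0.25 (SE). Trp53inp1 had a log2 fold change of 1.60 ± 0.65 and Zmat3 of 0.42 ± 0.19. Cdkn1a, the cell cycle inhibitor p21, was at 47.2 ± 19.4 CPM against 17.2 ± 8.74 CPM (SD, n = 3 each). No member passed over all genes or adjusted over the list alone. Without 5-day library 1, 4 passed over the list alone. Pro-apoptotic genes as a whole had a median of 0.07 (camera, adjusted p = 0.191), with 9 members higher and 7 lower. Replication-dependent histone genes were higher in 21 of 26 members and the list rose by a median of 0.44 (camera, adjusted p = 9.11e-07). The adjusted p = 0.146 with an estimated correlation ended that call. Hist1h2ah was at 37.0 ± 2.13 against 24.2 ± 4.98 CPM, and Hist1h2ac at 8.03 ± 1.98 against 5.23 ± 1.95 CPM (SD, n = 3 each). These genes are near-identical copies whose mRNAs mostly lack a poly(A) tail, so their counts in polyadenylated RNA are uncertain.

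Genes of cholesterol synthesis were lower in 15 of 15 members. The list fell by 0.49 on the log2 scale in the median (camera, adjusted p = 4.21e-12), and the call was lost at adjusted p = 0.359 with an estimated correlation. Log2 fold changes were -0.51 ± 0.19 (SE) for Hmgcs1, -0.45 ± 0.18 for Sc5d, -0.69 ± 0.32 for Idi1 and -0.70 ± 0.35 for Msmo1. None passed over all genes or adjusted over the list alone, and 5 did over the list alone without 5-day library 1. In a fit without that library and with the macrophage score of each library as a covariate, chosen after the results were seen, the median was -0.09 (adjusted p = 0.158). That score was itself higher on average at 24 h, so the covariate cannot be told apart from treatment. Nuclear-encoded respiratory chain genes were lower in 19 of 24 members and fell with a median of -0.13 (camera, adjusted p = 0.0301, and adjusted p = 0.892 with an estimated correlation). Ndufs1, a subunit of complex I, had a log2 fold change of -0.42 ± 0.24. The respiratory chain call was absent without untreated library 1 (median -0.10), untreated library 3 (-0.10), 24 h library 2 (-0.11) or 24 h library 4 (-0.09), with a filter at a mean of 5 CPM (-0.11), and with the replicate number as a block (0.06, adjusted p = 0.418).

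Markers of other cell types moved beside these groups. Schwann cell and glial markers rose, with 6 of 7 members higher and a median log2 fold change of 1.30 (camera, adjusted p = 1.57e-11). Their adjusted p = 0.0804 with an estimated correlation missed the threshold. Sox10, the glial lineage factor, was at 9.48 ± 4.55 CPM against 2.15 ± 0.359 CPM, and the neuregulin receptor Erbb3 at 6.30 ± 1.44 against 2.55 ± 1.65 CPM (SD, n = 3 each). Over the list alone 1 member passed, while 0 passed over all genes. Macrophage markers rose in the median by 0.75 with 14 of 16 higher (camera, adjusted p = 0.000294, and adjusted p = 0.892 with an estimated correlation). Without untreated library 2 their median was 0.56 (adjusted p = 0.0583). The lipid-sensing receptor Trem2 was at 21.2 ± 3.35 against 7.72 ± 2.02 CPM and the scavenger receptor Msr1 at 43.6 ± 7.57 against 19.9 ± 3.48 CPM. Cd163 was at 1.39 ± 0.307 against 5.79 ± 7.77 CPM (SD, n = 3 each for all 3 genes). Its log2 fold change of -2.05 became 0.08 without untreated library 3. Among genes of macrophages outside the lists, Gpnmb was at 239 ± 24.6 against 106 ± 13.8 CPM and Mmp12 at 48.9 ± 2.99 against 17.9 ± 4.65 CPM (SD, n = 3 each). The pan-leukocyte gene Ptprc was at 21.6 ± 5.14 against 18.0 ± 13.4 CPM (SD, n = 3 each).

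Interferon response genes were higher in 22 of 24 members and MHC class I presentation genes in 12 of 12. Both lists rose by a median of 0.85 (camera, adjusted p = 0.00737 and 0.00422, and adjusted p = 0.892 with an estimated correlation for each). They were led by 1 library. Summed over the interferon list, 24 h libraries 2, 3 and 4 held 95.2, 296 and 145 CPM, against 97.0 to 173 CPM in untreated tumours. Ifit3 was at 4.06 ± 4.28 against 1.10 ± 0.362 CPM, Bst2 at 13.9 ± 10.1 against 6.15 ± 2.54 CPM, Tap1 at 12.1 ± 11.6 against 4.12 ± 1.75 CPM and Nlrc5 at 5.32 ± 2.81 against 1.91 ± 0.755 CPM (SD, n = 3 each). In these 4 genes the SD at 24 h exceeded that of the untreated libraries. Without 24 h library 3 the medians were -0.07 for interferon (adjusted p = 0.944) and 0.17 for MHC class I genes (0.487), and without untreated library 2 they were 0.70 and 0.67, neither past the threshold.

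The remaining lists did not pass at 24 h with all 10 libraries. Medians were -0.08 for ribosome biogenesis genes (adjusted p = 0.0614), -0.05 for MYC metabolic and translation targets (0.178), 0.02 for cytosolic ribosomal proteins (0.654), -0.16 for adrenergic identity (0.464), 0.08 for neuronal differentiation (0.468) and -0.11 for the hypoxia response (0.21), with p from camera. Without 5-day library 1, ribosome biogenesis genes fell with a median of -0.07 (adjusted p = 0.0122, and adjusted p = 0.847 with an estimated correlation). MYC metabolic targets then fell with a median of -0.04 (adjusted p = 0.0478, and adjusted p = 0.852 with an estimated correlation). Mycn was at 92.2 ± 11.6 CPM against 96.9 ± 16.2 CPM, Myc at 2.72 ± 0.277 against 4.35 ± 1.56 CPM and the adrenergic enzyme Th at 125 ± 63.7 against 99.9 ± 22.2 CPM (SD, n = 3 each). Other medians were 0.17 for MHC class II (adjusted p = 0.424), 0.27 for inflammatory genes (0.423), -0.12 for immediate early genes (0.423), -0.02 for the unfolded protein and ATF4 response (0.423), 0.24 for mitochondrially encoded genes (0.0614), -1.41 for adipocyte markers (0.0697) and 0.14 for pericyte and smooth muscle markers (0.517). Adipocyte markers summed to 854 CPM in untreated library 3, 48.2 and 112 CPM in the other untreated libraries and 21.9 to 277 CPM at 24 h. In the unfolded protein and ATF4 list 9 members were higher and 11 lower, so its median hides members that went both ways. Adjusted over the list alone, 0 of its members passed with all libraries and 8 without 5-day library 1 (2 higher, 6 lower). Without that library, 7 macrophage, 4 histone, 2 Schwann cell, 1 replication and 1 pro-apoptotic member also passed over the list alone, beside those given above. Endothelial markers had a median of -0.06 with a mean of 0.05 (0.753), and fibroblast markers a median of 0.05 with a mean of -0.21 (0.746).

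**Figure D2:**
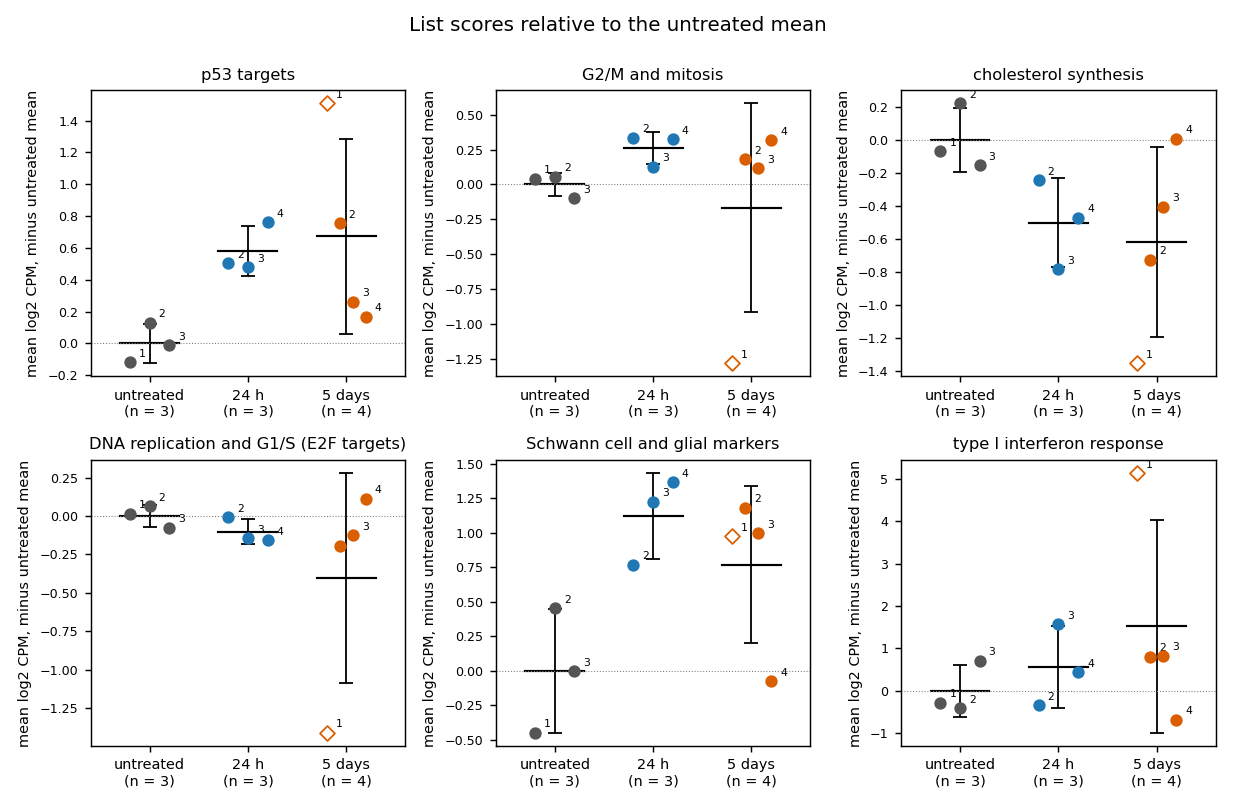
Mean log2 CPM over the genes of 6 lists in each library, minus the mean of the untreated libraries (points; numbers are replicate numbers), with the group mean and SD (untreated n = 3, 24 h n = 3, 5 days n = 4). For p53 targets the 24 h libraries lie between 0.48 and 0.76, above the untreated libraries (-0.12 to 0.13), and the open diamond, 5-day library 1, lies far from its group for p53 targets, mitosis, replication and the interferon response.

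**Figure D3:**
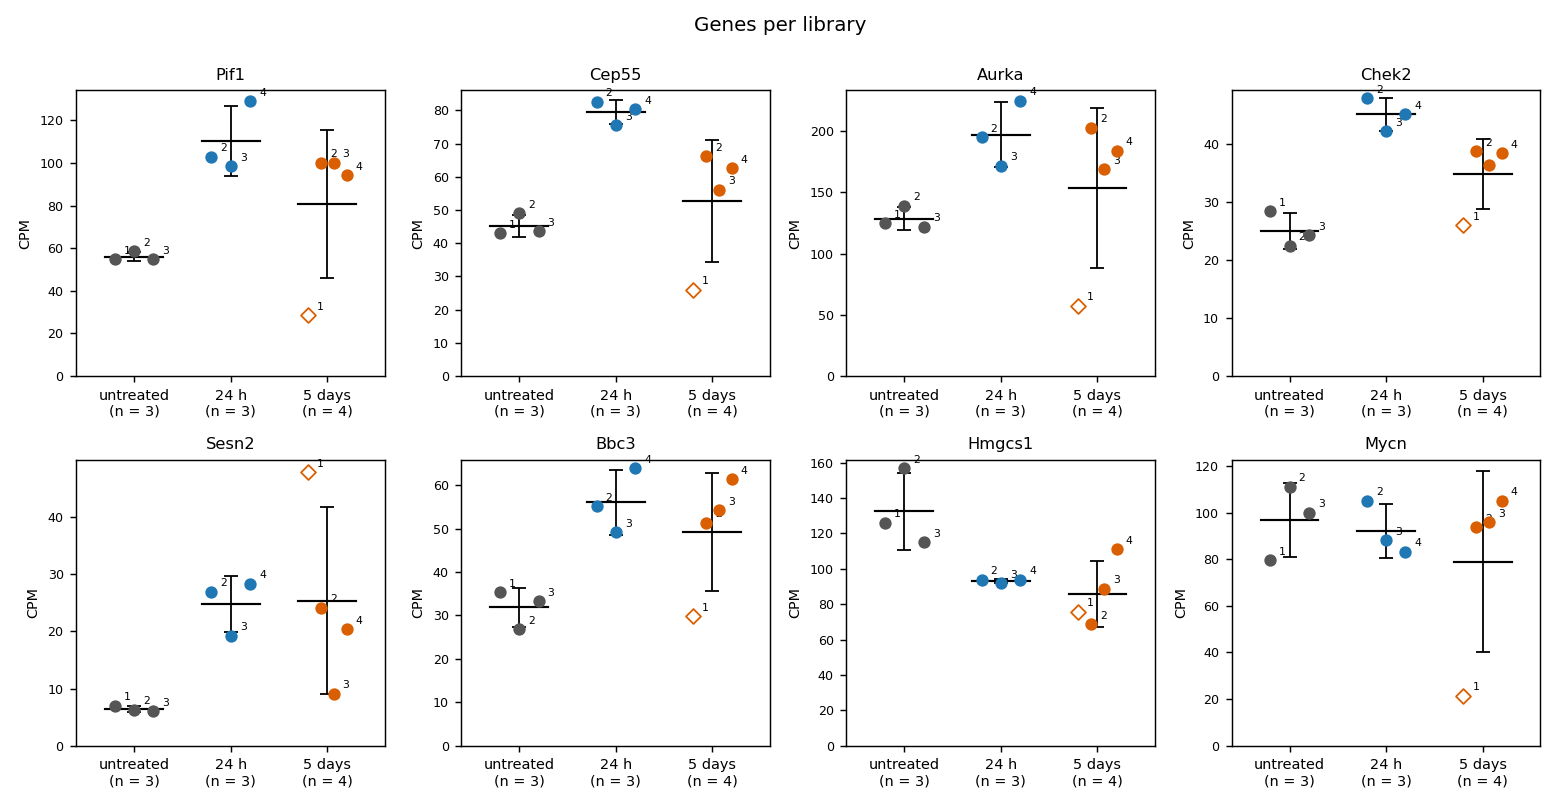
CPM of 8 genes in each library (points; numbers are replicate numbers), with the group mean and SD (untreated n = 3, 24 h n = 3, 5 days n = 4); the axes start at 0. Pif1 lies at 98.4 to 129 CPM at 24 h and 54.7 to 58.5 CPM in untreated tumours, and the open diamond, 5-day library 1, is at 28.6 CPM for Pif1 and 21.4 CPM for Mycn.

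The comparison of 5 days of treatment with no treatment asks what the tumours looked like after sustained dosing. Macrophage, interferon, MHC and adipocyte genes rose at 5 days and genes of replication, ribosome biogenesis, MYC targets and adrenergic identity fell, and both were carried in large part by library 1. These calls were lost at adjusted p = 0.538 to 0.581 with an estimated correlation. Without library 1 the interferon, MHC class II, replication, MYC target and ribosome biogenesis calls were absent. p53 targets, macrophage, Schwann cell and MHC class I genes then still rose, and cholesterol synthesis, adrenergic and ribosomal protein genes still fell, none of them with an estimated correlation (smallest adjusted p = 0.481). Sesn2 was at 25.4 ± 16.3 CPM (SD, n = 4) over all 4 libraries and at 17.9 ± 7.83 CPM (SD, n = 3) over libraries 2 to 4, against 6.44 ± 0.478 CPM (SD, n = 3) in untreated tumours. Dbh, which makes noradrenaline, was at 13.1 ± 6.07 CPM (SD, n = 4) and 15.6 ± 4.28 CPM (SD, n = 3) over the same libraries, against 48.0 ± 20.7 CPM (SD, n = 3).

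No gene of 14956 passed edgeR's quasi-likelihood test, with a smallest Benjamini-Hochberg adjusted p of 0.538. There were 1257 genes at an unadjusted p under 0.05 (954 higher, 303 lower; 748 by chance). DESeq2 called 27, of which 21 were higher. These included genes of skeletal muscle (Tnni2, Tnnt3, Myh2, Tcap, Mb), whose markers lay in libraries 2 and 4, and were chosen after their values were seen, together with Sesn2 (DESeq2 adjusted p = 0.048), Ephx1 and Mmp12 (0.0491 each). Without library 1, edgeR called 0 genes, with 1252 at an unadjusted p under 0.05. In simulated data with the spread of all 10 libraries, this test recovered 53% of genes changed 4-fold and 4.5% of those changed 2-fold at 5 days, and with the spread of the 9 libraries 81.8% and 65.7%. With the spread of all 10 libraries DESeq2 made 46 false calls at 5 days, and with that of the 9 libraries 24, against the 27 calls above. The simulations gave every library the same spread, while in the data 1 library lay apart. Neither number therefore counts the false calls among the 27.

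Macrophage markers rose by a median log2 fold change of 2.43 with 16 of 16 higher (camera, adjusted p = 8.90e-08, and adjusted p = 0.538 with an estimated correlation). Without library 1 the median was 0.52 (adjusted p = 1.25e-08, and adjusted p = 0.481 with an estimated correlation). The list then summed to 1622, 1591 and 989 CPM in libraries 2 to 4 against 575 to 975 CPM untreated, and by its mean log2 score library 4 lay within the untreated range. The clearance receptor Mertk was at 28.1 ± 14.0 CPM (SD, n = 3) in libraries 2 to 4 and 336 CPM in library 1, against 10.9 ± 2.71 CPM (SD, n = 3) untreated. Lysozyme Lyz2 was at 796 ± 210 CPM (SD, n = 3) and 7000 CPM in the same libraries, against 406 ± 111 CPM (SD, n = 3). Ptprc stood at 21.9 ± 8.09 CPM (SD, n = 3) in libraries 2 to 4, 323 CPM in library 1 and 18.0 ± 13.4 CPM (SD, n = 3) untreated. Interferon genes rose with 24 of 24 members higher and a median of 3.47 (camera, adjusted p = 1.75e-06, and adjusted p = 0.538 with an estimated correlation). Without library 1 their median was 0.38 (adjusted p = 0.0936). Ifit3 was at 135 CPM in library 1 and 3.67 ± 2.12 CPM (SD, n = 3) in the rest, and Rsad2 at 116 CPM and 8.20 ± 5.23 CPM (SD, n = 3). MHC class I genes rose by 2.93 in the median (camera, adjusted p = 3.46e-06, and adjusted p = 0.538 with an estimated correlation), and by 0.74 without library 1 (adjusted p = 0.000245, and adjusted p = 0.709 with an estimated correlation). Libraries 2, 3 and 4 held 493, 414 and 173 CPM of these genes against 161 to 284 CPM untreated, so library 4 lay within the untreated range. Nlrc5, the activator of MHC class I transcription, was at 72.5 CPM in library 1 and 5.76 ± 1.64 CPM (SD, n = 3) in the others, and the immunoproteasome gene Psmb8 at 35.0 and 2.36 ± 0.682 CPM (SD, n = 3).

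Several further lists rose only with library 1 in the fit, each at adjusted p = 0.538 with an estimated correlation unless stated. They were MHC class II (median 1.87, camera adjusted p = 0.0146, and 0.17 without library 1), inflammatory genes (2.01, 0.000764, and 0.33 without it), hypoxia genes (0.46, 0.00808, and 0.04 without it) and pro-apoptotic genes (0.52, 0.0314, and 0.07 without it). Immediate early genes rose by 1.14 (camera, adjusted p = 0.0177, and adjusted p = 0.61 with an estimated correlation), and had a median of 0.08 without library 1. Respiratory chain genes rose by 0.26 (0.00304) and adipocyte markers by 3.00 (0.0239), both with adjusted p = 0.581 with an estimated correlation, and their medians were 0.03 and 0.44 without library 1. In library 1 the cathepsin gene Ctss was at 1190 CPM, Vcam1 at 506 CPM, Atf3 at 111 CPM and the apoptosis initiator Casp8 at 91.1 CPM. Libraries 2 to 4 had 91.7 ± 39.0, 108 ± 10.1, 12.5 ± 5.18 and 6.81 ± 4.65 CPM for these genes (SD, n = 3 each). Pdk1, a hypoxia-induced kinase, was at 41.6 ± 5.98 CPM (SD, n = 3) in libraries 2 to 4 against 23.9 ± 1.61 CPM (SD, n = 3) untreated. The MHC class II, pro-apoptotic and respiratory chain calls were also absent without untreated library 2 (medians 1.53, 0.46 and 0.19), and the adipocyte call without untreated library 1 (2.46), untreated library 2 (2.56) or 5-day library 2 (3.17). Uqcrc1 was at 290 ± 28.3 against 268 ± 15.2 CPM and the brown fat gene Ucp1 at 86.3 ± 134 against 7.70 ± 9.88 CPM (SD, n = 3 each).

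p53 targets rose by a median of 0.60 at 5 days, with 22 of 26 higher (camera, adjusted p = 2.31e-06, and adjusted p = 0.538 with an estimated correlation). Without library 1 the median was 0.24 (adjusted p = 8.92e-07, and adjusted p = 0.481 with an estimated correlation), 4 members passed over the list alone and 0 over all genes. Libraries 2 to 4 had 22.3 ± 13.4 CPM of Trp53inp1 against 8.01 ± 1.66, 15.6 ± 10.9 CPM of the detoxifying enzyme gene Ephx1 against 4.35 ± 1.36, and 55.6 ± 5.16 CPM of Bbc3 against 31.9 ± 4.50 (SD, n = 3 each). Cdkn1a was at 33.6 ± 14.7 CPM (SD, n = 3) in these libraries and 185 CPM in library 1. Schwann cell markers rose by 0.88 in the median (camera, adjusted p = 0.000518, and adjusted p = 0.538 with an estimated correlation), and by 0.81 without library 1 (adjusted p = 0.000966, and adjusted p = 0.481 with an estimated correlation). By its mean log2 score library 4 lay within the untreated range here too. Sox10 was at 7.15 ± 5.42 CPM in libraries 2 to 4, against 2.15 ± 0.359 CPM (SD, n = 3 each). Mitotic genes had a median of -0.03 with all libraries (camera, adjusted p = 0.0675), and rose by 0.21 without library 1 (adjusted p = 2.40e-12, and adjusted p = 0.481 with an estimated correlation), when 13 of 39 passed over the list alone. Aurka was then at 185 ± 17.1 against 129 ± 9.17 CPM (SD, n = 3 each). Histones had a median of 0.10 (adjusted p = 0.0753) and rose by 0.23 without library 1 (adjusted p = 0.000966, and adjusted p = 0.683 with an estimated correlation).

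Cholesterol synthesis genes were lower at 5 days in 15 of 15 members and fell by 0.46 in the median (camera, adjusted p = 2.21e-08, and adjusted p = 0.538 with an estimated correlation). Without library 1 the median was -0.39 (adjusted p = 4.46e-08, and adjusted p = 0.481 with an estimated correlation). Libraries 2, 3 and 4 then held 866, 1131 and 1498 CPM of these genes against a mean of 1490 CPM untreated, so library 4 was not below that mean and library 2, which also held markers of other organs, was lowest. Log2 fold changes were -0.62 ± 0.17 (SE) for Hmgcs1, -0.46 ± 0.17 for Sc5d and -0.78 ± 0.30 for Idi1. Adrenergic identity genes fell by 0.60 in the median with 18 of 19 lower (camera, adjusted p = 3.20e-07, and adjusted p = 0.538 with an estimated correlation), and had a median of -0.29 without library 1 (adjusted p = 0.000875, and adjusted p = 0.481 with an estimated correlation). Dbh had a log2 fold change of -1.87 ± 0.57 and Tbx2, a core factor of this program, of -0.99 ± 0.42. Th was at 83.5 ± 20.1 CPM in libraries 2 to 4 against 99.9 ± 22.2, and Mycn at 98.1 ± 5.91 against 96.9 ± 16.2 CPM (SD, n = 3 each). Ribosomal protein genes fell in the median by 0.19 with 70 of 71 lower (camera, adjusted p = 1.91e-09, and adjusted p = 0.538 with an estimated correlation), and by 0.12 without library 1 (adjusted p = 8.92e-07, and adjusted p = 0.889 with an estimated correlation). Rpl15 was at 186 ± 7.91 CPM in libraries 2 to 4 against 236 ± 15.5 CPM (SD, n = 3 each).

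Lists that fell only with library 1 in the fit, each at adjusted p = 0.538 with an estimated correlation unless stated, were DNA replication and G1/S (median -0.29, camera adjusted p = 5.89e-08, and -0.03 without library 1), ATR pathway and recombination genes (-0.22, 0.000202, and -0.01 without it), ribosome biogenesis (-0.26, 1.75e-06, and -0.07 without it) and MYC metabolic targets (-0.23, 4.47e-05, and -0.05 without it). Neuronal differentiation genes fell by 0.19 (camera, adjusted p = 0.0146, and adjusted p = 0.545 with an estimated correlation), and had a median of -0.06 without it. In libraries 2 to 4, against untreated tumours, the replication licensing gene Cdc6 was at 32.0 ± 4.62 against 48.1 ± 7.46 CPM, Gins3 at 9.38 ± 1.74 against 14.9 ± 3.87 CPM and Chek1 at 42.7 ± 4.61 against 56.8 ± 4.50 CPM (SD, n = 3 each). Ddx10 was at 58.7 ± 8.55 against 69.5 ± 8.71 CPM, Tfam at 87.5 ± 3.15 against 103 ± 1.12 CPM, Ret at 21.4 ± 5.68 against 30.3 ± 12.2 CPM and the granin Scg2 at 9.74 ± 6.27 against 2.03 ± 0.876 CPM (SD, n = 3 each). Atr was at 55.2 ± 3.45 against 50.1 ± 8.37 CPM and Myc at 2.30 ± 1.01 against 4.35 ± 1.56 CPM (SD, n = 3 each), with Myc at 26.0 CPM in library 1. Lists that did not pass in either fit were the unfolded protein response (0.19, adjusted p = 0.12), mitochondrially encoded genes (0.18, 0.466), endothelial (0.91, 0.0753), fibroblast (1.87, 0.0963) and pericyte markers (1.16, 0.113). Adjusted over the list alone with all libraries, 3 unfolded protein response genes, 3 T cell, 3 adrenal cortex, 1 pericyte and 1 skeletal muscle marker passed, beside 0 over all genes. Without library 1 these numbers were 7, 0, 0, 0 and 1. Beside members given above, 2 macrophage, 2 adrenergic, 2 hypoxia (1 of them higher), 1 pro-apoptotic and 1 histone gene then also passed over the list alone.

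The direct comparison of 5 days with 24 h asks how the profile moved on between the times. With all libraries, genes of mitosis, replication, ribosome biogenesis, MYC targets, ribosomal proteins and adrenergic identity were lower at 5 days, and interferon, MHC, inflammatory, hypoxia, respiratory chain, macrophage and adipocyte genes were higher. Without library 1 few of these differences were left. Ribosomal protein and adrenergic genes were still lower and respiratory chain and hypoxia genes still higher, each at adjusted p = 0.89 with an estimated correlation, while the interferon and macrophage medians changed sign. Gata3, a factor of the sympathetic lineage, was at 63.3 ± 7.49 CPM (SD, n = 3) in 5-day libraries 2 to 4 and 52.8 ± 21.9 CPM (SD, n = 4) in all 4, against 93.9 ± 3.84 CPM (SD, n = 3) at 24 h.

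No gene passed edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.581, and 942 genes at an unadjusted p under 0.05 where chance gives 748). DESeq2 called 3, which were Tnni2, a skeletal muscle gene, higher at 5 days, and Pabpc1 and Gm21887 lower, all chosen after their values were seen. In simulated data DESeq2 made 41 false calls in this comparison with the spread of all 10 libraries and 24 with that of the 9 libraries without library 1. Without library 1, edgeR called 0 genes, with 1140 at an unadjusted p under 0.05. All 18 list calls of this comparison were lost at adjusted p = 0.575 with an estimated correlation. Adjusted over the list alone, 1 pericyte, 1 hepatocyte and 1 skeletal muscle marker passed, and 0, 0 and 1 without library 1. Without it, 2 neuronal genes (1 of them higher) and 1 adrenergic gene (lower) also passed over the list alone.

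Ribosomal proteins fell by 0.22 in the median at 5 days relative to 24 h (camera, adjusted p = 1.01e-11, and adjusted p = 0.575 with an estimated correlation), and by 0.15 without library 1 (adjusted p = 7.68e-08). Rpsa was at 457 ± 19.6 CPM in 5-day libraries 2 to 4 against 560 ± 64.6 CPM at 24 h (SD, n = 3 each). Adrenergic genes fell by 0.45 with 19 of 19 lower (camera, adjusted p = 2.57e-06, and adjusted p = 0.575 with an estimated correlation), and by 0.17 without library 1 (adjusted p = 0.0222). Dbh had a log2 fold change of -1.64 ± 0.57 (SE), Gata3 of -0.83 ± 0.32 and Th of -0.67 ± 0.32. Respiratory chain genes rose by 0.35 (camera, adjusted p = 2.57e-06, and adjusted p = 0.575 with an estimated correlation), and by 0.15 without library 1 (adjusted p = 0.00242). Ndufs1 was at 77.7 ± 1.56 against 56.8 ± 13.2 CPM (SD, n = 3 each). Hypoxia genes rose by 0.73 (camera, adjusted p = 3.00e-04, and adjusted p = 0.575 with an estimated correlation), and by 0.21 without library 1 (adjusted p = 0.0274). These 4 calls without library 1 were lost at adjusted p = 0.89 with an estimated correlation. Pdk1 was at 41.6 ± 5.98 against 28.9 ± 6.73 CPM and the glycolytic regulator Pfkfb3 at 67.0 ± 24.3 against 43.9 ± 4.58 CPM (SD, n = 3 each). Without library 1, mitochondrially encoded genes (median -0.40, adjusted p = 0.000919) and p53 targets (-0.14, adjusted p = 0.00986) also fell, each at adjusted p = 0.89 with an estimated correlation. With all libraries the mitochondrially encoded genes had a median of -0.06 (adjusted p = 0.367).

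The other differences rested on library 1. Mitotic genes fell by 0.30 relative to 24 h with 39 of 39 lower (camera, adjusted p = 4.69e-09, and adjusted p = 0.575 with an estimated correlation), and had a median of -0.06 without library 1 (adjusted p = 0.0742). Cdc25b was at 67.2 ± 7.19 against 76.0 ± 1.57 CPM, Cenpa at 222 ± 29.7 against 260 ± 16.7 CPM and Aurka at 185 ± 17.1 against 197 ± 26.2 CPM in 5-day libraries 2 to 4 and at 24 h (SD, n = 3 each). Replication genes fell by 0.17, ATR pathway genes by 0.18, ribosome biogenesis and MYC metabolic targets each by 0.16 and neuronal genes by 0.33 (camera, adjusted p = 2.98e-05, 0.00175, 0.000745, 0.00176 and 0.00175, and adjusted p = 0.575 with an estimated correlation for each). Their medians without library 1 were 0.06, 0.01, 0.04, 0.05 and -0.14. Gins3 was at 9.38 ± 1.74 against 13.9 ± 3.78 CPM, Rad9a at 24.6 ± 1.39 against 32.4 ± 4.51 CPM, Nop56 at 248 ± 26.2 against 280 ± 2.18 CPM, Ptma at 1223 ± 86.0 against 1345 ± 190 CPM and Elavl4 at 163 ± 13.4 against 222 ± 30.8 CPM (SD, n = 3 each). Interferon genes rose by 2.76, MHC class I by 2.04, MHC class II by 1.70, inflammatory genes by 1.53, immediate early genes by 1.13, macrophage markers by 1.66 and adipocyte markers by 4.40 (camera, adjusted p = 0.000443, 0.00151, 0.0439, 0.00234, 0.00176, 0.000641 and 0.00151, and adjusted p = 0.575 with an estimated correlation for each). Without library 1 these medians were -0.31, -0.04, 0, 0.09, 0.10, -0.16 and 2.05, none past the threshold. The unfolded protein response rose by 0.28 (camera, adjusted p = 0.0168, and adjusted p = 0.575 with an estimated correlation) and had a median of 0.10 without library 1. Without 24 h library 2, the ATR pathway, ribosome biogenesis, MYC target, interferon, MHC class I, MHC class II and adipocyte calls were also absent (medians -0.11, -0.06, -0.10, 2.39, 1.59, 1.31 and 3.83). The MHC class II call was absent without 24 h library 4 (1.41) or 5-day library 2 (1.87), and that of the unfolded protein response without 24 h library 4 (0.25) or 5-day library 4 (0.28). Cd163 was at 132 CPM in library 1 and 4.70 ± 4.06 CPM in the rest, against 1.39 ± 0.307 CPM at 24 h (SD, n = 3 each). Psmb8 was at 2.36 ± 0.682 against 1.56 ± 1.36 CPM, Tnfaip3 at 7.42 ± 2.43 against 5.32 ± 0.900 CPM, Nr4a1 at 8.40 ± 3.83 against 5.60 ± 0.181 CPM and Trib3 at 4.28 ± 0.909 against 2.37 ± 0.515 CPM in libraries 2 to 4 and at 24 h (SD, n = 3 each). Lists that did not pass were histones (median -0.28 with a mean of 0.12, adjusted p = 0.0859), pro-apoptotic genes (0.20, 0.255), cholesterol synthesis (-0.08, 0.347) and endothelial (0.69, 0.121), fibroblast (1.83, 0.184), pericyte (1.02, 0.249) and Schwann cell markers (-0.33, 0.212). The p53 list had a median of 0.11 and a mean of 0.39 while its test leaned lower (adjusted p = 0.893).

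Both treatment times were compared with the same 3 untreated libraries. With 0 genes called at either time by edgeR's quasi-likelihood test and 0 at 24 h by DESeq2, a count of genes called at both times can only be 0 and says nothing on a shared response. The overlap of independent lists of these lengths is 0, as was the highest number in 20 simulations of unchanged groups against the untreated libraries. Across genes, which are not independent replicates, the log2 fold changes at 24 h and 5 days had a correlation of 0.32, where unchanged groups sharing the untreated libraries gave 0.54. The covariance was 0.104 against 0.15 in the simulations, a difference of -0.0453. Those simulations gave every library, the untreated ones included, the spread that 5-day library 1 widens. Values below them with all libraries therefore say nothing on the real fold changes. Without 5-day library 1 the correlation was 0.55 against 0.50 simulated, and the covariance 0.0758 against 0.0596, a difference of 0.0162. The sign was the same at both times for 62.1% of genes with all libraries, where the simulations gave 67.9%, and for 65.4% without library 1, where they gave 66.7%. With 3 untreated libraries the group could not be split into parts of 2 or more, so part of any excess may come from the shared libraries.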

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

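The tests of other splits of the libraries, of 5-day library 1, of a lower share of tumour cells and of macrophage RNA without 5-day library 1 were chosen after the results were seen, while those of gene length and GC content were set before their results were seen.

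In the 5-day group, 1 library lay far from the other 3, by a gap over Dixon's 95% critical value, for 34 of 53 genes and 38 lists examined. In 33 of these 34 it was library 1. Chance would give about 4.6 if CPM values were normally distributed and the items unselected. Many of the genes were named for a small p in comparisons with this group, and some are members of the lists. The number 4.6 is therefore no test of the 34. In CPM, library 1 had 111 for Atf3, 91.1 for Casp8, 132 for Cd163, 185 for Cdkn1a, 1190 for Ctss, 135 for Ifit3, 7000 for Lyz2, 336 for Mertk and 26 for Myc. It had 130 for Ndufs1, 72.5 for Nlrc5, 35 for Psmb8, 323 for Ptprc, 116 for Rsad2, 59.7 for Tnfaip3 and 506 for Vcam1. Mycn was at 21.4 CPM, with the nearest library at 93.6. Summed CPM in library 1 was 3420 for interferon, 5120 for MHC class I, 3140 for MHC class II, 1060 for inflammatory, 1310 for immediate early and 1350 for hypoxia genes. For markers it was 143 for T cells, 60.4 for NK cells, 227 for B cells, 13700 for macrophages, 262 for dendritic cells, 141 for neutrophils, 19200 for fibroblasts, 34.4 for kidney tubule and 9130 for adipocytes. Neuronal genes summed to 1140 CPM, with the nearest library at 3200. In library 2, adrenal cortex markers summed to 1940 CPM, with the nearest at 176.

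The state of 5-day library 1 was weighed first. Its macrophage markers exceeded its Schwann cell markers by 2.64 on the log2 scale relative to the other 5-day libraries, beyond the bound of 1.09 from the spread of the other 9. The highest such ratio was that of adipocyte markers (4.07), whose SD over the other 9 libraries was 2.14. Mbp made up much of the Schwann cell sum, at 89.5 CPM in library 1 and 70.5 to 93 CPM in the other 5-day libraries. The gap of this 1 pair of lists therefore cannot decide on a lower tumour share with the other cells in their usual mix. Adrenergic genes were at 0.251, replication genes at 0.361 and mitosis genes at 0.403 of the untreated mean, with Mycn at 21.4 CPM. These values argue against tissue free of sympathetic and dividing cells, but cannot tell tumour cells from other such cells. That lower tumour share, a tumour or tissue piece rich in immune, fibroblast and fat cells, and a response of that tumour to treatment stay open. So do tissue without tumour cells, poor RNA and a wrong label. Mitochondrial genes held 4.81% and the 10 most abundant genes 7.36% of its counts, the highest shares of the 10 libraries, which do not decide on RNA quality. Ddx3y was at 4.97 CPM there, and the labels give no sex that could decide on a wrong label.

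The p53, mitosis and cholesterol lists at 24 h were weighed next. After removal of a trend on gene length and GC content (14950 of 14956 genes had a length), their medians were 0.46, 0.26 and -0.48, with camera adjusted p of 7.12e-10, 1.49e-06 and 7.12e-10, which argues against these biases as the whole cause. With the macrophage score as a covariate in a fit without 5-day library 1, which otherwise sets the slope, the p53 and mitosis medians of 0.53 and 0.26 became 0.35 and 0.37 (adjusted p = 1.71e-09 and 2.53e-30), which argues against macrophage RNA as their whole cause, while that of cholesterol synthesis went from -0.48 to -0.09 (adjusted p = 6.15e-13 and 0.158; with that library in the fit -0.38 and 0.000105). A lower share of tumour cells, or dilution of tumour RNA by macrophage RNA, would lower replication and cholesterol genes alike if treatment itself left replication genes unchanged. The lower quartile of replication genes was -0.18, against an upper quartile of -0.44 for cholesterol synthesis. On that condition these quartiles argue against dilution as the whole cause. The condition was not tested, and the drugs inhibit kinases of mitosis and replication stress. The macrophage score was itself 0.362, 0.87 and 0.815 in the 24 h libraries, against -0.487 to 0.426 in untreated ones. As a covariate it thus takes up part of the treatment contrast, and the change to -0.09 cannot set macrophage RNA apart from treatment. Batches, which the labels do not give, treatment and, for the cholesterol list, RNA of macrophages or a lower share of tumour cells stay open.

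Other splits of the same libraries into groups of the same sizes were tested for the counts of calls. Where the real split called 0 genes every split had as many, 10 of 10 at 24 h (highest other 0), 35 of 35 at 5 days (highest other 3) and 35 of 35 for 5 days against 24 h (highest other 0), so these counts decide nothing. At 24 h, 7 of 10 splits had as many lists (9; highest other 18). With only the compared groups in the fit this held for 1 of 10 splits (7 genes, highest other 1), and without 5-day library 1 for 1 of 10 (2 genes, highest other 0). At 5 days, 26 of 35 splits had as many lists (20; highest other 25), and for 5 days against 24 h 25 of 35 (18; highest other 24), so chance cannot be excluded for these counts of lists.

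Single lists at 24 h were ranked over the same 10 splits by their camera p with a preset correlation. The p53, mitosis, cholesterol, Schwann cell and macrophage lists had their smallest p in the real split (1 of 10 splits). As small a p was found in 2 of 10 splits for histones, 3 for the respiratory chain, 5 for MHC class I and 7 for interferon genes. In this exact permutation ranking the real p and the smallest p of the other splits for the first 5 lists were 9.82e-15 and 1.48e-08, 1.26e-08 and 1.50e-08, 3.11e-13 and 1.03e-09, 1.74e-12 and 1.01e-09, and 6.53e-05 and 0.000139. At 24 h, 10 splits are too few for a share under 0.05.

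The direct test of 5 days against 24 h set the effects of the times apart for 18 lists, none of them with an estimated correlation. Median differences were -0.17 for replication, -0.30 for mitosis, -0.18 for ATR pathway genes, -0.16 for ribosome biogenesis, -0.16 for MYC metabolic targets, -0.22 for ribosomal proteins, -0.45 for adrenergic and -0.33 for neuronal genes. They were 2.76 for interferon, 2.04 for MHC class I, 1.70 for MHC class II, 1.53 for inflammatory genes, 1.13 for immediate early genes, 0.28 for the unfolded protein response, 0.73 for hypoxia, 0.35 for the respiratory chain, 1.66 for macrophages and 4.40 for adipocytes. Without 5-day library 1, 6 lists were called. Ribosomal protein, adrenergic, hypoxia and respiratory chain genes were among the 18, while mitochondrially encoded genes and p53 targets were not.

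Lists with too few tested genes for a test also held signal, at over 5 times the highest untreated library. In 5-day library 1 these were T cell (143 against 19.6 CPM), NK cell (60.4 against 1.92), B cell (227 against 18.3), dendritic cell (262 against 26) and neutrophil markers (141 against 9.78). In 5-day library 2 they were adrenal cortex (1940 against 76.1), hepatocyte (429 against 76.4) and skeletal muscle markers (525 against 4.69). Skeletal muscle markers also reached 184 CPM in 5-day library 4. No explanation of these was tested.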

How the results depend on the processing

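Chosen after the results were seen were the fits without 5-day library 1 at 24 h or with an estimated correlation, those without 5-day libraries 1 and 2, and those with quality weights per library. The cause was not tested for any change below, except that fewer libraries were fitted where some were left out.

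For called lists, alternatives kept direction and call in 113 of the results at 24 h, lost the call in 28 and reversed in 2. At 5 days these counts were 235, 74 and 10, and for 5 days against 24 h 185, 79 and 24. For named genes, 545, 568 and 310 results were the same, 6, 12 and 3 reversed, and 15 and 2 passed the threshold at 24 h and 5 days. DESeq2's size factors in edgeR and both filters moved no count of genes called (0 each) and no count of lists by over 1.5 times (7 to 10 at 24 h, 20 to 28 at 5 days, 17 to 25 for 5 days against 24 h).

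At 24 h, 0 genes were called with edgeR (263 at an unadjusted p under 0.05) and 0 with DESeq2, but 7 with only the compared groups, 3 without 5-day libraries 1 and 2 and 3 with quality weights. Leaving out 1 library gave 0 to 2 genes, the 2 without 5-day library 1. At 5 days DESeq2 called 27 genes, and for 5 days against 24 h 3, where leaving out 5-day libraries 1 and 2 gave 2. Lists called at 24 h went from 9 to 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and 5-day library 1 left out, and 14 with quality weights. At 5 days the 20 lists became 0, 0 and 0 under the first 3 of these and 13 without 5-day libraries 1 and 2, and ranged from 9 (without library 1) to 28 when 1 library was left out. For 5 days against 24 h the 18 lists became 0, 0 and 0, 10 without 5-day libraries 1 and 2 and 7 with quality weights, and ranged from 6 (without library 1) to 23.

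With the replicate number as a replicate block, 20 lists were called at 24 h, 23 at 5 days and 10 for 5 days against 24 h, and 0 genes in each. Under this replicate block Myc at 24 h was 0.12, mitosis -0.06 and the respiratory chain 0.06, and Aurka at 5 days -0.02. In this fit number 1 joins untreated library 1 to 5-day library 1, with no 24 h library of that number. For numbers 2 and 3, mitosis scores at 24 h were 0.335 and 0.126, against 0.056 and -0.097 untreated. Respiratory chain scores were -0.137 and -0.03, against -0.106 and 0.048. For both numbers, mitosis was thus higher and the respiratory chain lower at 24 h. Whether the numbers pair the samples stayed open. Over 8 pairs of libraries with the same number, deviations from the group means correlated from -0.395 to 0.247 (median -0.062, against 0.041 for other pairs), 2 of 8 were over 0.1 and 0 libraries correlated best with their own number. The 2 over 0.1 were the same-number pairs of untreated and 24 h libraries (0.211 and 0.247). Other pairs of these groups had -0.291 to 0.049. Pairs with a 5-day library use deviations from a mean that 5-day library 1 shifts, so they cannot exclude pairing.

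Quality weights reversed, at 5 days, Myc (-0.90), Atr (0.17), the respiratory chain (0) and adipocyte markers (-0.41). For 5 days against 24 h they reversed Mycn (0.10), replication (0.03), ATR pathway genes (0.01), ribosome biogenesis (0.06), MYC metabolic targets (0.04), interferon (-0.09), MHC class II (-0.10) and macrophage genes (-0.14).

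Without 5-day libraries 1 and 2, reversed values at 5 days were 0.05 for Mycn, -1.25 for Myc, 0.18 for Atr, -0.03 for Ptprc, 0.02 for ATR pathway, -0.06 for neuronal (by its test), -0.92 for MHC class II, 0.04 for immediate early (by its test), 0.01 for hypoxia (by its test), -0.04 for respiratory chain and -2.64 for adipocyte genes. For 5 days against 24 h they were 0.12 for Mycn, 0.10 for replication, 0.07 for ATR pathway, 0.09 for ribosome biogenesis, 0.09 for MYC metabolic, -0.59 for interferon, -0.18 for MHC class I, -1.11 for MHC class II, 0.04 for immediate early (by its test), -0.31 for macrophage and -1.20 for adipocyte genes.

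Leaving out 1 library at a time reversed some values. At 24 h the ranges were -2.51 to 0.08 for Cd163, -0.20 to 0.05 for Mycn, -0.27 to 0.02 for Atr, -0.18 to 0.54 for Th and -0.05 to 1.07 for Ptprc. At 5 days they were -0.46 to 0.02 for Mycn, -0.91 to 1.27 for Myc, -0.15 to 0.14 for Atr, -0.09 to 0.85 for Ddx3y and 0.08 to 1.46 for immediate early genes, reversed by its test. For 5 days against 24 h they were -0.38 to 0.09 for Mycn, -0.37 to 0.06 for replication, -0.31 to 0.01 for ATR pathway, -0.30 to 0.04 for ribosome biogenesis, -0.28 to 0.05 for MYC metabolic, -0.31 to 3.67 for interferon, 0 to 2.67 for MHC class II and -0.16 to 2.02 for macrophage genes. At 24 h the p53, mitosis, histone, cholesterol and Schwann cell calls were kept whichever library of the compared groups or 5-day library 1 was left out.

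Depth limits genes near the floor of 0.527 to 0.538 CPM. Psmb8, at 0.928 ± 0.399 CPM (SD, n = 3) in untreated tumours, lies near it.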

Other observations

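The comparisons of all 6 treated libraries other than 5-day library 1 with the 3 untreated libraries were chosen after the results were seen, except the count of genes with no overlap, which was set before its result was seen.

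Genes that separated treated from untreated libraries without overlap are given here by known function and were chosen after their values were seen, and 8 of 84 splits had as many such genes. Apoe, an apolipoprotein, had means of 926 CPM in treated and 402 CPM in untreated libraries, and Abca1, a cholesterol exporter, of 93.1 and 49.7 CPM. Lyz2 had means of 766 and 406 CPM, Mertk of 25.5 and 10.9 CPM and the lysosomal pump subunit Atp6v0d2 of 26.8 and 10.8 CPM. Pif1 had 104 and 56.0 CPM, Aurka 191 and 129 CPM and the linker histone Hist1h1c 19.9 and 7.66 CPM. Lower in treated libraries were Cdc6 (31.6 and 48.1 CPM), Mfap2 (33.9 and 52.4 CPM) and Ntng2 (34.4 and 64.8 CPM).

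A hypothesis was that p53, mitosis, cholesterol, Schwann cell and macrophage lists shifted at both treatment times. Differences of list scores were 0.49, 0.23, -0.44, 0.91 and 0.65 on the log2 scale, and 6, 6, 5, 5 and 4 of 6 treated libraries lay beyond every untreated library. A two-sided exact permutation test over 84 splits, whose smallest p is 0.0119, gave adjusted p of 0.321, 0.321, 0.386, 0.321 and 0.429 over 27 lists. With 84 splits and 27 lists, a single list at the smallest p could not pass, so these tests leave the hypothesis open. With 5-day library 1 among the treated libraries the differences were 0.63, 0.02, -0.57, 0.92 and 1.18, with adjusted exact permutation p of 0.45, 0.983, 0.45, 0.338 and 0.78 over 120 splits, so the mitosis and macrophage differences depend on this library. Among 12019 genes, 555 had no overlap between treated and untreated libraries (249 higher, 306 lower), where chance gives 2.4%, or 286, and 8 of 84 splits had as many (highest other 1038), so the count itself gives no support for a shift beyond other structure of the samples.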
